A study of Caenorhabditis elegans with 4 samples.

How the data were processed

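The analysis covered 4 whole-animal samples of Caenorhabditis elegans, all from young adults of the rege-1(rrr13) strain: 2 fed mock double-stranded RNA and 2 fed double-stranded RNA against ets-4 from the first larval stage, per the labels' protocols. Total RNA was extracted with Trizol and libraries were made with the ScriptSeq v2 kit, per the labels' protocols. The authors deposited raw read counts per gene, whole numbers with totals of 25060376 to 27163269 per library, for 20182 genes named by WormBase gene ID. The aligner, the counting tool, the genome build and the use of strand in counting are not given in the sources used here, so counts of overlapping, antisense and near-identical genes are uncertain. Per the file headers, the count table also gives a width per gene, a length in bases in another unit than the counts. Of the widths, 96.6% are multiples of 3 and 72.7% lie within 3 bases of the annotated coding length, so for most genes it matches a coding length. What it is for the others, annotated pseudogenes among them, is not known, and it was not used in any test. The second deposited table holds log2 values, which equal log2 of the count scaled to the mean library total plus 8, to within 5.15e-14. No column of either table was left without a sample or a meaning (unmatched columns: 0).

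Gene symbols were found for 18778 gene IDs (93.0%) in the gene name table of the reference, and positions for 19513 IDs in the WBcel235 annotation (Ensembl release 115), matched by gene ID only. The other 669 IDs were kept without a position. Genes without a symbol are named by their sequence name. Of the IDs, 720 are annotated as pseudogenes.

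Groups were taken from the sample titles. The main comparison, written before the data were examined, was ets-4 RNAi against mock RNAi in edgeR 4.0.16 (R 4.3.3): genes with low counts were removed with filterByExpr, which left 14756 genes and removed 5426. Libraries were scaled by TMM factors (0.999, 1.006, 0.990 and 1.005), and a robust quasi-likelihood F test was made with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors were derived from the log2 fold change and the F statistic. For genes with few counts in a group they can be narrower than counting error alone. CPM are counts per 1e+06 of the TMM-scaled library totals. Intervals on ratios of counts are exact conditional 95% intervals, and for 0 counts a floor of 3 counts per library was used. Both cover counting error only, since reads without molecular identifiers are not independent molecules. At these depths 3 counts in a library correspond to about 0.1 CPM, which limits the folds of the deepest falls.

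Genes to be named were set by a rule written before the data were examined: ets-4, rege-1, the 12 largest rises and the 12 largest falls among genes past the threshold with the same direction in every pair of libraries and a mean of at least 50 counts, and up to 4 members of each reported list with the smallest adjusted p. Genes named outside this rule are marked in the text. The 39 gene lists were also fixed before the data were examined, from general knowledge of the worm, and some genes are in more than 1 list. Lists with at least 3 tested members, 38 of them, were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with the correlation estimated from the data, and with fry, each with Benjamini-Hochberg adjustment over the lists. fry tests whether the genes of a list move one way on balance and does not compare a list with other genes.

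The fit was tested on simulated counts for ets-4 RNAi against mock RNAi with the real means and library sizes, in 5 data sets of 14756 genes with 200 changed genes each. With dispersions drawn around the fitted trend, edgeR called 28.4% of genes changed 1.5-fold, 55.8% of those changed 2-fold and 86.1% of those changed 4-fold, and 8.12% of its calls were false. With the dispersions estimated gene by gene, these were 50.1%, 76.7% and 92.4%, and 13.9% of calls were false. In simulated lists, camera at the preset correlation called 5 of 5 changed lists and 0 of 100 unchanged ones. Every gene of a changed list was raised 1.5-, 2- or 4-fold, so these lists do not show how often smaller shifts would be called. The simulated genes varied independently, so the simulation does not test the preset correlation on lists whose genes vary together.

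Alternatives named before the data were examined were other scalings (DESeq2-style factors, upper-quartile factors, totals only), no low-count filter and a stricter one at 5 CPM in 2 libraries, vitellogenin and major sperm protein genes left out of the library sizes, the replicate number as a block, each library left out in turn, DESeq2 1.42.0, limma voom, limma on the deposited log2 values, and other thresholds. With 1 library of a group left out, the spread comes from the remaining pair, and the lone library is assumed to vary like it. Member counts of each list without each library, the scan of gene families by symbol stem and the tests of explanations were added after the data were seen. Groups of 2 libraries allow no test for an outlying library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.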

Results

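Whole young adult Caenorhabditis elegans of the rege-1(rrr13) strain were profiled by RNA sequencing after feeding on bacteria that carried double-stranded RNA against ets-4 or a mock control. The strain carries a mutation in rege-1, which encodes a ribonuclease of the Regnase family, and ets-4 encodes a transcription factor of the ETS family. The study set out to find the genes under ets-4 that account for the phenotype of the rege-1 mutant. Each group held 2 libraries. Total counts were 26655999 and 27163269 for mock RNAi replicates 1 and 2, and 25060376 and 26510262 for ets-4 RNAi replicates 1 and 2. Of 20182 genes in the count table, 14756 had enough counts to be tested. Because the labels do not say that replicates came from separate cultures, the p-values measure only the spread between these samples, which may be technical. Fold changes are given as log2 of ets-4 RNAi over mock RNAi ± SE with n = 2 libraries per group, and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, two-sided.

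The ets-4 transcript itself (WBGene00017687, chromosome X, 6518883 to 6522667, plus strand, WBcel235 annotation) was 4.75-fold lower in the ets-4 RNAi libraries. It had 2002 and 1921 counts in mock RNAi replicates 1 and 2 and 321 and 471 counts in ets-4 RNAi replicates 1 and 2. Mean levels were 72.8 ± 3.44 CPM (SD, n = 2) with mock RNAi and 15.3 ± 3.35 CPM with ets-4 RNAi, a log2 change of -2.25 ± 0.14 (edgeR adjusted p = 4.82e-05). Any sequenced fragments of the fed double-stranded RNA would be included in these counts. The rege-1 transcript (WBGene00016260, chromosome I, 6954414 to 6961139, minus strand) fell with it, from 16.7 ± 0.169 to 3.66 ± 0.447 CPM. Its counts were 441 and 459 with mock RNAi and 83 and 106 with ets-4 RNAi, a 4.55-fold decrease (log2 -2.18 ± 0.15, edgeR adjusted p = 3.45e-05). Both transcripts were lower in each ets-4 RNAi library than in each mock RNAi library.

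With knockdown of ets-4 more transcripts fell than rose, and most of the changes of at least 2-fold were falls. Among the 12 deepest losses were saposin-like proteins (spp-12, spp-9), C-type lectins (clec-70, clec-72, clec-60, clec-52), the aspartyl protease asp-12 and enzymes of fatty acid oxidation (ech-9, acox-1.5). Among the 12 largest gains were the annotated pseudogene H17B01.3, the cytochrome P450 genes cyp-35A2 and cyp-34A7, the lectin clec-218, the dehydrogenase dhs-26 and the pud-3 and pud-4 genes. edgeR called 2817 genes at an adjusted p under 0.05, 19.1% of those tested, of which 1161 were higher and 1656 lower. Among the 918 that changed at least 2-fold, 153 were higher and 765 lower, so that 83.3% of them fell. At least 4-fold changes were found in 42 higher and 252 lower genes, and at least 16-fold changes in 5 higher and 50 lower genes. Genes that fell at least 2-fold held 7.59% and 7.53% of the counts in mock RNAi replicates 1 and 2 but 1.51% and 1.70% in ets-4 RNAi replicates 1 and 2. Genes that rose at least 2-fold went from 0.585% and 0.533% to 2.11% and 1.82%. All 2817 called genes had both ets-4 RNAi libraries on the same side of both mock RNAi libraries, which a call with 2 libraries per group nearly requires. Such separation held for 63.8% of all tested genes, where 33.3% would be separated by chance. The count depended on each library. It was 891 without mock RNAi replicate 1, 796 without mock RNAi replicate 2, 4177 without ets-4 RNAi replicate 1 and 5352 without ets-4 RNAi replicate 2, and the count of at least 2-fold changes was 551, 534, 985 and 1434 in the same order.

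The 12 largest falls took transcripts that were present at 6.75 to 3091 CPM in mock RNAi animals down to between 0 and 11.7 CPM. The saposin-like gene spp-12 went from 358 ± 49.4 to 0.176 ± 0.0364 CPM (SD, n = 2), a 2037-fold difference (log2 -10.96 ± 0.19, edgeR adjusted p = 6.06e-08). The enoyl-CoA hydratase family gene ech-9 fell 1573-fold, from 1239 ± 56.2 to 0.788 ± 0.373 CPM (log2 -10.59 ± 0.16). The glucuronosyltransferase gene ugt-18 fell 938-fold (log2 -9.86 ± 0.10), and the aspartyl protease gene asp-12 fell 705-fold, from 3091 ± 243 to 4.38 ± 0.493 CPM (log2 -9.46 ± 0.11, edgeR adjusted p = 3.22e-09). Peroxisomal acyl-CoA oxidase acox-1.5 fell 86.1-fold, from 1004 ± 34.9 to 11.7 ± 3.09 CPM (log2 -6.42 ± 0.19). Among the lectins, clec-70 fell 1599-fold (log2 -10.59 ± 0.15), clec-72 fell 176-fold (log2 -7.43 ± 0.15) and clec-52 fell 93.5-fold (log2 -6.54 ± 0.23). Several of these genes kept few counts, and their counting error was wider than the SE. The 95% counting intervals were 1077 to 4474-fold for spp-12, 1145 to 2165-fold for ech-9 and 641 to 1438-fold for ugt-18. For clec-70 and clec-72 they were 805 to 3678-fold and 108 to 307-fold. The protein-coding gene Y39G8B.7 fell 59.2-fold, from 182 counts in each mock RNAi library to 1 and 5 counts (95% counting interval 26.3 to 159). The lectin clec-60 kept 1 count in each ets-4 RNAi library against 241 and 329, a ratio of 270.9 with a 95% counting interval of 74.9 to 2249. No count of spp-9 was found with ets-4 RNAi against 231 and 265 with mock RNAi, and with 3 counts per library as the limit it was at least 78.7-fold lower. The annotated pseudogene F56D6.15 likewise had 0 counts against 259 and 272, at least 84.3-fold lower. It lies between clec-67 and clec-70 on chromosome IV, and reads of clec-70, clec-71, clec-72 and this pseudogene could be split among near-identical copies, so their separate values are uncertain.

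Among the 12 largest rises, pud-3 reached the highest level. It rose 7.39-fold, from 462 ± 26.6 to 3419 ± 70.6 CPM (SD, n = 2; log2 2.89 ± 0.06, edgeR adjusted p = 4.29e-08), and its neighbour pud-4 rose 8.41-fold, from 97.9 ± 4.56 to 824 ± 34.04 CPM (log2 3.07 ± 0.06). The pud genes are close copies, so reads could be assigned to either. The P450 gene cyp-35A2 rose 28.5-fold, from 0.611 ± 0.120 to 17.4 ± 1.27 CPM (log2 4.82 ± 0.20), and cyp-34A7 rose 6.99-fold (log2 2.79 ± 0.26). The lectin clec-218 rose 17.98-fold, from 5.34 ± 0.359 to 96.1 ± 0.245 CPM (log2 4.17 ± 0.09), and the short-chain dehydrogenase dhs-26 rose 17.6-fold (log2 4.14 ± 0.34). C30G12.2 rose 11.8-fold, drd-50 rose 10.4-fold, lact-6 rose 9.75-fold and W02H3.1 rose 8.40-fold. The steepest rise was that of H17B01.3, an annotated pseudogene, with 2 and 4 counts against 396 and 461 (log2 7.17 ± 0.27, 150-fold). T22B7.7 rose 7.38-fold (log2 2.88 ± 0.34, edgeR adjusted p = 0.0282), with 895 and 1157 counts against 5351 and 9179, and this call was lost without mock RNAi replicate 1 (adjusted p = 0.134) or replicate 2 (adjusted p = 0.133), and without the low-count filter (adjusted p = 0.0627). The other genes named in these groups of 12 kept their calls without any single library.

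**Figure D1:**
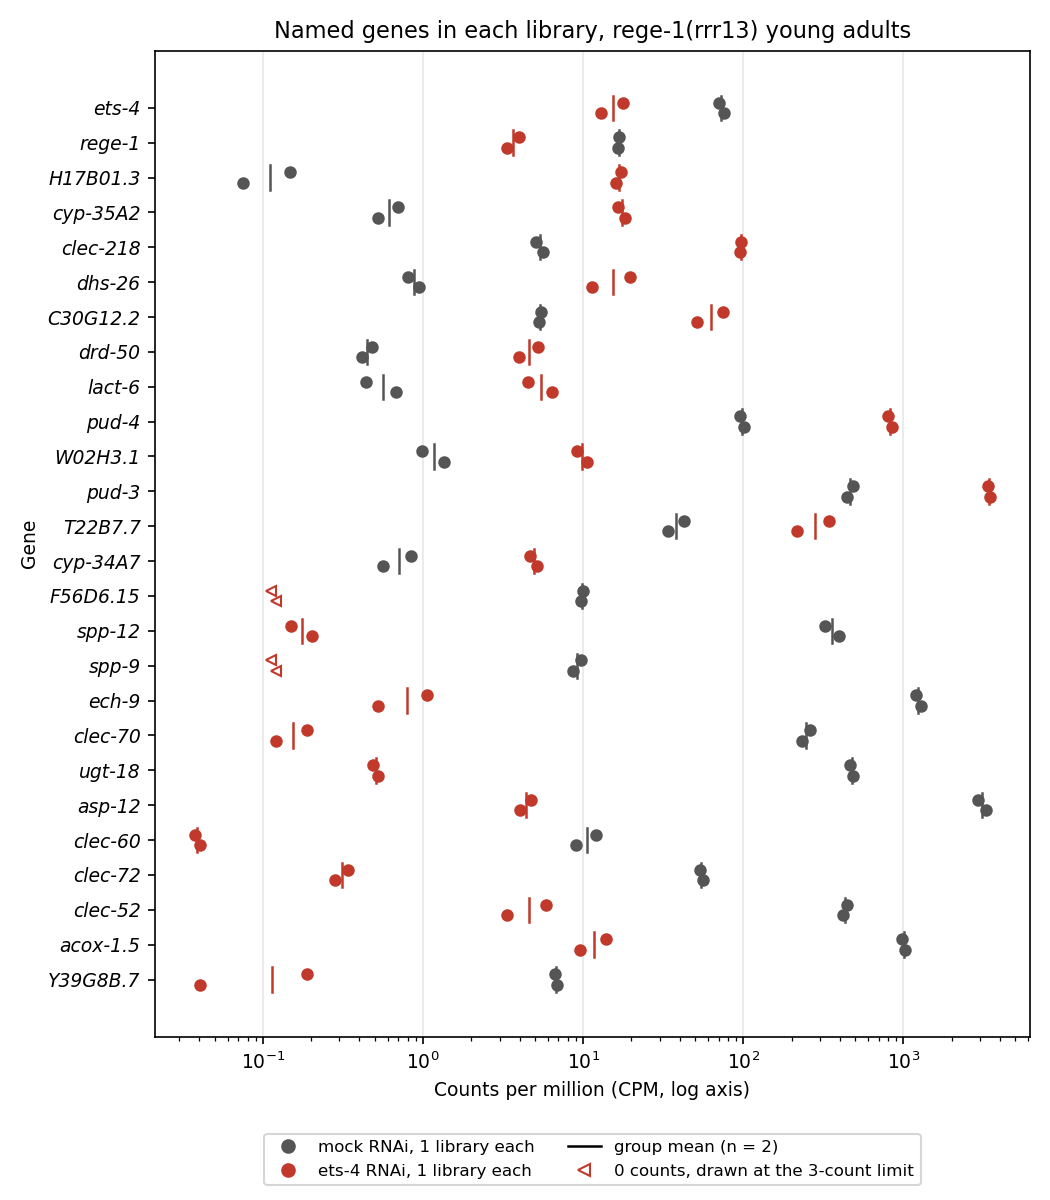
CPM (log axis) of ets-4, rege-1, the 12 genes with the largest rises and the 12 with the largest falls, 1 point per library, with mock RNAi in grey and ets-4 RNAi in red; vertical bars are group means (n = 2), and open triangles mark libraries with 0 counts, drawn at the 3-count limit. For each gene the points of the 2 groups do not overlap, which the rule for picking the rises and falls required. The mean of asp-12 goes from 3091 to 4.38 CPM.

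Gene lists fixed before the data were examined were tested next with camera at a preset inter-gene correlation of 0.01. Of 38 lists with at least 3 tested members, 16 passed an adjusted p of 0.05, 8 higher and 8 lower. None of the 16 calls held when camera estimated the correlation from these 4 libraries, where the smallest adjusted p was 0.311. With 2 libraries per group that version has few residual degrees of freedom and little power. A call lost in it therefore does not show that a list did not move. By fry 9 of the 16 passed, and so did 3 lists without a camera call, those of ETS factors, lipid droplets and neuron markers. The ETS list holds ets-4, the gene targeted by the RNAi, so its fry call does not show a response of the family. Counts of members are those past the edgeR threshold over all tested genes, followed by the count adjusted over the list alone.

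More genes of the intestine marker list fell than rose. The list was set from general knowledge, and not all of its members are specific to the intestine. Of 23 intestine markers, 13 fell and 4 rose (13 and 4 adjusted over the list alone; median log2 -0.41, camera adjusted p = 1.84e-23, adjusted p = 0.311 with an estimated correlation). Proteases had the smallest adjusted p. The cathepsin B-like cysteine protease cpr-1 fell from 661 to 53.0 CPM (log2 -3.64 ± 0.06). The aspartyl proteases asp-3 (-3.18 ± 0.05), asp-1 (-2.65 ± 0.06) and asp-2 (-2.72 ± 0.07) fell from between 2352 and 5463 CPM. The asp genes share sequence, so single values are less certain than their common direction. The 4 markers that rose, named after their values were seen, were also protease genes, asp-4 (0.49 ± 0.06), cpr-5 (0.49 ± 0.08), cpr-6 (0.44 ± 0.05) and cpl-1 (0.30 ± 0.05). Without mock RNAi replicate 1, 2 of the markers rose.

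Most genes in the list of intestinal immune effectors fell too. The list was set from general knowledge, and whole-animal RNA does not show in which tissue a member was expressed. Of 39 tested, 26 fell and 3 rose (28 and 5 adjusted over the list alone; median -1.08, camera adjusted p = 2.56e-43, adjusted p = 0.311 with an estimated correlation), and the median stayed at -1.08 with spp-9 held at its bound. The lysozyme lys-4 fell from 116 to 4.21 CPM (-4.78 ± 0.09), spp-23 from 241 to 13.6 CPM (-4.14 ± 0.08) and spp-2 from 129 to 12.8 CPM (-3.34 ± 0.08), beside spp-12. The 3 that rose, named after their values were seen, were lys-7 (2.23 ± 0.10), sysm-1 (1.89 ± 0.18) and thn-2 (1.35 ± 0.17). Without ets-4 RNAi replicate 2, 5 members rose. Among 127 C-type lectins, 50 fell and 9 rose (55 and 9 adjusted over the list alone; median -0.48, camera adjusted p = 8.80e-19, adjusted p = 0.403 with an estimated correlation). The lectin clec-63 fell from 2192 to 414 CPM (-2.41 ± 0.06). Without mock RNAi replicate 1, 5 lectins rose, and without mock RNAi replicate 2, 3 rose. The lectin genes also differed between the ets-4 RNAi libraries, by a median of -0.17 for replicate 1 minus replicate 2.

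Lipid enzymes of several kinds fell. In the list for mitochondrial and peroxisomal beta-oxidation, 20 of 39 members fell and 4 rose (21 and 4 adjusted over the list alone; median -0.29, camera adjusted p = 2.04e-12, adjusted p = 0.403 with an estimated correlation). The largest falls past the threshold were those of ech-9 and acox-1.5, and by adjusted p ech-9 was followed by hacd-1, a hydroxyacyl-CoA dehydrogenase (-2.22 ± 0.06, 199 to 42.6 CPM), and the peroxisomal genes dhs-28 (-1.38 ± 0.06, 345 to 132 CPM) and acox-3 (-1.29 ± 0.06, 100.03 to 40.9 CPM). The 4 that rose were acox-1.3 (6.79 to 31.2 CPM), acox-1.2 (1.14 ± 0.12), cpt-4 (0.83 ± 0.17) and cpt-6 (0.55 ± 0.09), named after their values were seen. Members that fell numbered 14 without mock RNAi replicate 1 and 12 without replicate 2, and those that rose were 2 without mock RNAi replicate 1 and 7 without ets-4 RNAi replicate 1. In fatty acid synthesis, desaturation and elongation, 13 of 23 fell and 2 rose (15 and 2 adjusted over the list alone; median -0.31, camera adjusted p = 2.82e-04, adjusted p = 0.526 with an estimated correlation). The delta-9 desaturase fat-5 fell from 39.9 to 5.83 CPM (-2.78 ± 0.12), the elongase elo-2 from 298 to 166 CPM (-0.85 ± 0.07) and the desaturase fat-6 from 442 to 256 CPM (-0.79 ± 0.07). With either mock RNAi library left out, 8 members of this list fell and 1 rose.

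Of 12 lipase genes, 5 fell and 0 rose (7 and 0 adjusted over the list alone; median -0.57, camera adjusted p = 6.47e-08, adjusted p = 0.403 with an estimated correlation). The lipases lipl-1 (-3.37 ± 0.07, 220.1 to 21.4 CPM) and lipl-2 (-1.92 ± 0.06, 130.4 to 34.3 CPM) changed most clearly. The call of lipl-5 (-1.29 ± 0.17) was lost without mock RNAi replicate 2 and that of lipl-6 (-1.21 ± 0.28) without either mock RNAi library and in DESeq2 (adjusted p = 0.0628). Lipases that fell numbered 3 and 2 without mock RNAi replicates 1 and 2, and 9 without ets-4 RNAi replicate 2. Of 18 lipid binding proteins, 5 fell and 3 rose (7 and 3 adjusted over the list alone; median -0.08, camera adjusted p = 0.0331, adjusted p = 0.547 with an estimated correlation). dsc-4, the homolog of the large subunit of microsomal triglyceride transfer protein, fell from 608 to 149 CPM (-2.03 ± 0.06), lbp-5 fell by 1.35 ± 0.10 and far-3 fell by 1.88 ± 0.15, while far-5 rose (0.53 ± 0.08; not without mock RNAi replicate 2). Its median was 0.003 without ets-4 RNAi replicate 1. That list's camera call was lost without ets-4 RNAi replicate 2 (adjusted p = 0.0636), without the low-count filter (0.100), with the filter at 5 CPM (0.0505), in limma voom (0.211) and on the deposited log2 values (0.317). Without mock RNAi replicates 1 and 2 it had 3 and 3 members that fell and 1 and 0 that rose, and without ets-4 RNAi replicate 2 it had 8 and 6. The list for lipid droplets and triglyceride synthesis went both ways, with 4 of 11 lower and 3 higher (5 and 3 adjusted over the list alone; median -0.10, camera adjusted p = 0.346, fry adjusted p = 0.0492). The acyltransferase acl-1 fell (-1.74 ± 0.08, 74.3 to 22.3 CPM), as did acs-22 (-0.80 ± 0.06) and the lipin lpin-1 (-0.60 ± 0.05), and the diacylglycerol acyltransferase dgat-2 rose (1.67 ± 0.09, 13.1 to 41.7 CPM). Without either mock RNAi library 1 member of that list rose, and without ets-4 RNAi replicate 1, 2 rose.

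Genes of the molting cycle and of the larval cuticle fell. Of 34 tested, 19 fell and 0 rose (24 and 0 adjusted over the list alone; median -1.17, camera adjusted p = 3.08e-09, adjusted p = 0.573 with an estimated correlation; fry adjusted p = 0.0566). The apical matrix genes noah-1 (-1.35 ± 0.07, 66.3 to 25.97 CPM), fbn-1 (-1.81 ± 0.12, 49.9 to 14.2 CPM) and noah-2 (-1.01 ± 0.12) fell, and so did the protease inhibitor gene mlt-11 (-2.02 ± 0.19). These genes were not at the same level in both ets-4 RNAi libraries: replicate 1 was lower than replicate 2 by a median of 0.68 on the log2 scale (list median -0.68 for replicate 1 minus replicate 2), while the mock RNAi libraries differed by 0.03. The number that fell was 7 without either mock RNAi library, 30 without ets-4 RNAi replicate 1 and 33 without ets-4 RNAi replicate 2. Cuticle collagens did not pass as a list (camera adjusted p = 0.872). Of 109, 24 rose and 11 fell (26 and 14 adjusted over the list alone), and median (-0.47), mean (-0.39) and camera direction (up) differed in sign. Abundant collagens such as col-122 (0.49 ± 0.05, 1971 to 2769 CPM) and col-184 (0.42 ± 0.05, 672 to 902 CPM) rose, whereas col-176 fell (-1.75 ± 0.19, 6.23 to 1.85 CPM). The collagens differed between the ets-4 RNAi libraries by a median of -0.63, and without ets-4 RNAi replicate 2 the list passed as lower (median -0.77, camera adjusted p = 1.11e-08, where the other libraries left out gave 0.902 to 0.974). Collagens that rose and fell numbered 13 and 1 without mock RNAi replicate 1, 11 and 2 without mock RNAi replicate 2, 29 and 41 without ets-4 RNAi replicate 1, and 31 and 63 without ets-4 RNAi replicate 2.

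Of the 6 vitellogenin genes, 4 rose and 0 fell (4 and 0 adjusted over the list alone; median 1.41, camera adjusted p = 1.70e-04, adjusted p = 0.573 with an estimated correlation; fry adjusted p = 0.0988). vit-1 went from 2107 ± 256 to 7364 ± 1777 CPM (SD, n = 2; 1.81 ± 0.23), and vit-3 (2.01 ± 0.21), vit-4 (1.73 ± 0.21) and vit-5 (1.09 ± 0.18) rose with it. vit-2 (0.30 ± 0.20) and vit-6 (0.16 ± 0.12) did not pass the test and are named after their values were seen. The genes vit-3, vit-4 and vit-5 are near-identical, so the division of reads among them is uncertain. All vitellogenins together took 3.48% and 2.99% of counts in mock RNAi replicates 1 and 2 and 4.85% and 3.81% in ets-4 RNAi replicates 1 and 2, and their median was 0.41 higher in ets-4 RNAi replicate 1 than in replicate 2. Their number of calls was 3 without mock RNAi replicate 1, 1 without mock RNAi replicate 2 and 6 without ets-4 RNAi replicate 2, with the call of vit-1 lost in both mock cases and those of vit-4 and vit-5 without mock RNAi replicate 2. Without the low-count filter 1 of the 6 was called.

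Of 30 oocyte and eggshell genes, 17 rose and 0 fell (25 and 0 adjusted over the list alone; median 0.29, camera adjusted p = 5.40e-05, adjusted p = 0.604 with an estimated correlation; fry adjusted p = 0.104). The yolk receptor gene rme-2 rose from 747 to 954 CPM (0.35 ± 0.05), the eggshell genes cbd-1 from 1783 to 2241 CPM (0.33 ± 0.05) and cpg-1 from 1231 to 1622 CPM (0.40 ± 0.06), with calls lost without mock RNAi replicate 2 and, for cpg-1, also without replicate 1. Of this list 2 rose without mock RNAi replicate 1 and 0 without replicate 2, and the list's median was 0.14 higher in ets-4 RNAi replicate 1 than in replicate 2. Genes of germline proliferation and meiosis rose in 10 of 32 cases and fell in 0 (11 and 0 adjusted over the list alone; median 0.15, camera adjusted p = 0.0142, adjusted p = 0.604 with an estimated correlation; fry adjusted p = 0.0838), among them the P granule helicase glh-1 (0.36 ± 0.05; call lost without mock RNAi replicate 2). That number was 1 without mock RNAi replicate 1, 0 without replicate 2 and 16 without ets-4 RNAi replicate 2, and the list's camera adjusted p was 0.0505 with the filter at 5 CPM. Of 12 major sperm protein genes, which are near-identical copies, 5 rose and 0 fell (5 and 0 adjusted over the list alone; median 0.80, camera adjusted p = 0.0206, adjusted p = 0.573 with an estimated correlation; fry adjusted p = 0.0887). Among them was msp-142, which went from 9.12 to 15.2 CPM (0.74 ± 0.20; call lost without either mock RNAi library, with the filter at 5 CPM (adjusted p = 0.0664), in limma voom (0.0542) and on the deposited log2 values (0.0538)). Without mock RNAi replicates 1 and 2 the sperm protein calls were 1 and 0, and without ets-4 RNAi replicate 2 camera gave an adjusted p of 0.0978. Of 33 other sperm genes, 7 rose and 0 fell (7 and 0 adjusted over the list alone; median 0.33, camera adjusted p = 2.28e-03, adjusted p = 0.604 with an estimated correlation; fry adjusted p = 0.132), among them ssq-4 (0.66 ± 0.09). This number was 3 without mock RNAi replicate 1, 1 without replicate 2 and 17 without ets-4 RNAi replicate 1. Both sperm lists were lower in ets-4 RNAi replicate 1 than in replicate 2, by medians of -0.36 for major sperm proteins and -0.24 for the others. Early zygotic embryo genes did not pass (0 rose and 1 fell of 18; 0 and 0 adjusted over the list alone; camera adjusted p = 0.528), with 5 rising without ets-4 RNAi replicate 2 and 3 falling without ets-4 RNAi replicate 1.

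Ribosomal protein genes rose together by a small factor. Of 79, 66 rose and 0 fell (69 and 0 adjusted over the list alone), with a median of 0.30 (camera adjusted p = 3.49e-13, adjusted p = 0.311 with an estimated correlation). Examples were rpl-25.2 (0.49 ± 0.05, 1485 to 2091 CPM), rps-26 (0.41 ± 0.05, 605 to 803 CPM), rps-4 (0.38 ± 0.05, 1718 to 2233 CPM) and rpl-2 (0.41 ± 0.05, 759 to 1009 CPM). Left without mock RNAi replicate 1, 26 rose, and without replicate 2, 16 rose. Nuclear genes of the mitochondrial respiratory chain rose in 6 of 32 cases and fell in 1 (9 and 1 adjusted over the list alone; median 0.15, camera adjusted p = 0.0400, adjusted p = 0.573 with an estimated correlation). They included cyc-2.1 (0.28 ± 0.06) and cox-5A (0.26 ± 0.06). No member was called without either mock RNAi library, and the list's camera adjusted p was 0.0609 without mock RNAi replicate 1, 0.0755 without ets-4 RNAi replicate 2 and 0.111 with the filter at 5 CPM. Without ets-4 RNAi replicate 1, 13 members rose, and without replicate 2, 12 rose and 5 fell. Core and linker histone genes, many of them identical copies, rose in 7 of 29 cases and fell in 0 (8 and 1 adjusted over the list alone, median 0.25, camera adjusted p = 0.0559). This result sat near the threshold, and the list passed camera with the replicate number as a block (adjusted p = 0.0292). The histone list passed camera with upper-quartile factors (adjusted p = 0.0453), totals only (0.0450), no low-count filter (0.0190), limma voom (7.08e-03), the deposited log2 values (0.0197), without mock RNAi replicate 1 (0.0386) and without ets-4 RNAi replicate 2 (3.32e-05, 20 rising), and 4 members fell without ets-4 RNAi replicate 1. No histone gene was called without either mock RNAi library, and the list differed between the ets-4 RNAi libraries by a median of 0.29.

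Detoxification enzymes went in both directions. Of 55 cytochrome P450 genes, 17 rose and 9 fell (17 and 10 adjusted over the list alone; median 0.07, mean 0.16, camera adjusted p = 0.0181, adjusted p = 0.573 with an estimated correlation). cyp-34A9 rose from 68.7 to 240 CPM (1.80 ± 0.08) and cyp-25A1 from 8.12 to 37.1 CPM (2.19 ± 0.12), whereas cyp-13B1 fell from 29.5 to 0.949 CPM (-4.95 ± 0.16). The cyp-35A genes are close copies and their separate values are uncertain. In this list 12 rose and 5 fell without mock RNAi replicate 1, 11 rose and 4 fell without replicate 2, and the list's adjusted p was 0.0689 on limma voom values and 0.0807 on the deposited log2 values by camera, and 0.0566 by fry. UDP-glucuronosyltransferases rose in 23 of 63 cases and fell in 13 (25 and 13 adjusted over the list alone), with a median of 0.19 but a mean of -0.10, and camera gave no call (adjusted p = 0.108). ugt-41 (17.8 to 82.1 CPM) and ugt-63 (1.88 ± 0.09, 19.6 to 72.3 CPM) rose, while ugt-18 and ugt-44 (-1.63 ± 0.06, 761 to 246 CPM) fell. Without mock RNAi replicates 1 and 2, 13 and 14 rose, and without ets-4 RNAi replicate 1 the list passed camera (adjusted p = 0.0196), as it did without the low-count filter (8.86e-03), in limma voom (0.0412) and on the deposited log2 values (0.0398). Phase II and oxidative stress genes did not pass (3 rose and 4 fell of 19; 3 and 4 adjusted over the list alone; camera adjusted p = 0.528), although gst-10 rose (1.07 ± 0.11). None of them fell without either mock RNAi library, and 2 and 1 rose without mock RNAi replicates 1 and 2.

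**Figure D2:**
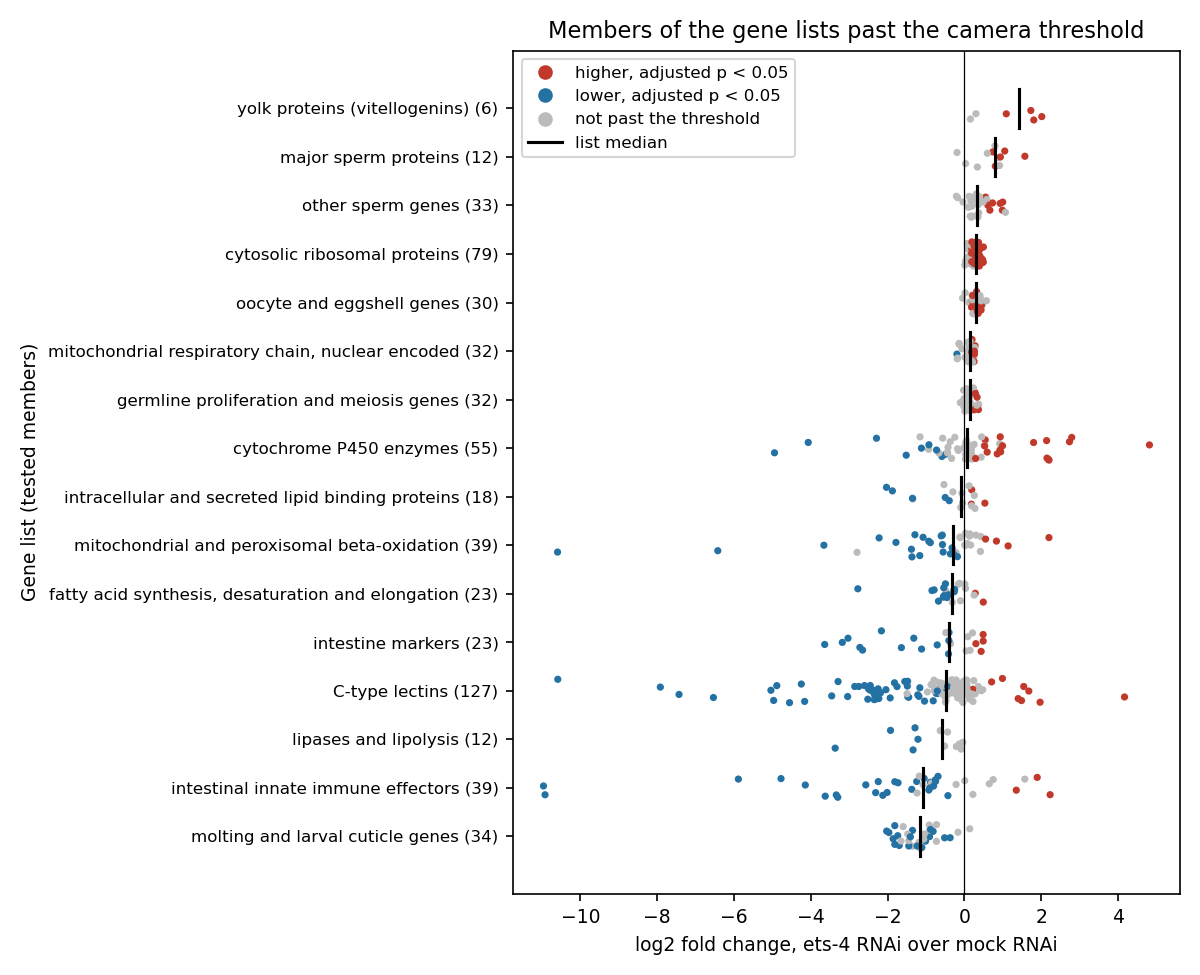
log2 fold change of ets-4 RNAi over mock RNAi for each tested member of the 16 gene lists past the camera threshold at the preset correlation, 1 point per gene (red higher, blue lower, grey not past an adjusted p of 0.05); black bars are list medians and the number of tested members is in parentheses. Medians run from -1.17 for molting genes to 1.41 for yolk proteins, and the lists of lipid and immune genes have long tails of falling genes.

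The remaining lists gave no camera call in the main test, and several held strong changes in both directions. Genes reported as activated by DAF-16, the FOXO factor of insulin signalling, split into 2 that rose and 3 that fell of 16 (3 and 3 adjusted over the list alone; camera adjusted p = 0.362): the lysozyme lys-7 (2.23 ± 0.10, 10.1 to 47.2 CPM) and the ferritin ftn-1 (2.69 ± 0.24) rose, while the catalase ctl-2 fell (-1.59 ± 0.12, 74.2 to 24.7 CPM). Of 10 genes reported as repressed by DAF-16, 4 rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.116), with dod-24 up from 92.1 to 196 CPM (1.09 ± 0.08) and the insulin-like gene ins-7 down from 9.60 to 1.69 CPM (-2.50 ± 0.18). In iron and heme handling 3 rose and 2 fell of 12 (4 and 2 adjusted over the list alone; camera adjusted p = 0.549). The ferroportin fpn-1.2 fell (-2.50 ± 0.14) and the heme transporter hrg-1 rose (1.64 ± 0.16). Intestinal transporters and metal response genes rose in 3 and fell in 5 of 17 cases (4 and 7 adjusted over the list alone; camera adjusted p = 0.0966), with falls in the ABC transporter gene abt-4 (-2.52 ± 0.09, 217 to 37.9 CPM) and the transcription factor gene pqm-1 (-1.71 ± 0.12). Epidermal antimicrobial peptides rose in 3 and fell in 5 of 14 cases (4 and 6 adjusted over the list alone; camera adjusted p = 0.793), with nlp-27 higher (0.69 ± 0.05). Carbohydrate genes rose in 8 and fell in 3 of 29 cases (11 and 4 adjusted over the list alone; camera adjusted p = 0.108), among them a rise of pck-1 (0.56 ± 0.07). Of 7 ETS factors, ets-6 rose (0.25 ± 0.07; not without either mock RNAi library or with the filter at 5 CPM, adjusted p = 0.0526) and ets-4 itself fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.240, fry adjusted p = 0.0492). The other member that fell over the list alone was ets-10, 2.85-fold lower with 19 and 14 counts against 6 and 5 (95% counting interval 1.41 to 6.27; edgeR adjusted p = 0.0592, and 0.0287 without ets-4 RNAi replicate 1). Without mock RNAi replicates 1 and 2 the numbers that rose and fell were 2 and 1 and 2 and 1 for iron genes, 1 and 4 and 1 and 4 for transporters, 1 and 1 and 1 and 1 for epidermal peptides, and 2 and 2 and 2 and 2 for carbohydrate genes. Without ets-4 RNAi replicates 1 and 2, DAF-16 activated genes had 4 and 3 and 5 and 4. Without ets-4 RNAi replicate 1, 4 iron genes fell, 5 transporter genes rose, 13 carbohydrate genes rose and 2 ETS genes fell, and without replicate 2, 8 transporter genes fell and 2 ETS genes rose. Camera passed the DAF-16 repressed list without ets-4 RNAi replicate 1 (adjusted p = 0.0388) and the transporter list without mock RNAi replicate 2 (adjusted p = 0.0455). It passed the carbohydrate list without the low-count filter (adjusted p = 8.05e-03), in limma voom (0.0103) and on the deposited log2 values (0.0197). With the replicate number as a block, camera passed the DAF-16 repressed list (adjusted p = 0.0122) and the transporter list (0.0435). Iron genes differed between the ets-4 RNAi libraries by a median of 0.41.

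Stress response genes and markers of other tissues also gave no camera call in the main test, though some passed in other settings. Heat shock proteins rose in 3 and fell in 1 of 12 cases (5 and 1 adjusted over the list alone; camera adjusted p = 0.0926), and 7 genes of the endoplasmic reticulum unfolded protein response fell with 0 rising of 15 (7 and 0 adjusted over the list alone; camera adjusted p = 0.295), pdi-6 (-0.44 ± 0.05) and enpl-1 (-0.41 ± 0.05) among them. For mitochondrial unfolded protein response genes 1 rose and 1 fell of 10 (1 and 1 adjusted over the list alone; camera adjusted p = 0.852), and for autophagy and lysosome genes 1 rose and 3 fell of 23 (1 and 3 adjusted over the list alone; camera adjusted p = 0.946). Muscle markers fell in 6 and rose in 1 of 24 cases (8 and 3 adjusted over the list alone; camera adjusted p = 0.395), with unc-54, the body wall myosin, lower (-0.51 ± 0.07, 1725 to 1215 CPM). Neuron markers fell in 3 and rose in 0 of 30 cases (3 and 0 adjusted over the list alone; camera adjusted p = 0.346, fry adjusted p = 0.0496), FMRFamide-like neuropeptides fell in 2 and rose in 0 of 29 (1 and 0 adjusted over the list alone; 0.362), and insulin-like peptides rose in 1 and fell in 1 of 19 (1 and 1 adjusted over the list alone; 0.872). RNA interference genes rose in 6 and fell in 2 of 36 cases (6 and 2 adjusted over the list alone; camera adjusted p = 0.359). The Regnase family, with 2 tested members, was too small for a list test, and besides rege-1 it held rde-8 (0.07 ± 0.06). Without either mock RNAi library 0 members of the mitochondrial unfolded protein response, autophagy, neuron, FMRFamide and RNA interference lists were called, and 2 of the endoplasmic reticulum list fell. Without mock RNAi replicates 1 and 2, 3 and 2 muscle markers fell and 3 and 0 heat shock proteins rose. Without ets-4 RNAi replicate 2, 13 muscle markers, 9 neuron markers and 7 FMRFamide-like neuropeptides fell, 11 RNA interference genes, 9 autophagy genes and 8 heat shock proteins rose, and the heat shock list passed camera (adjusted p = 0.0338), as it did without mock RNAi replicate 1 (adjusted p = 0.0325). Without ets-4 RNAi replicate 1, 9 autophagy genes and 4 RNA interference genes fell and 3 muscle markers rose. No insulin-like gene rose without either mock RNAi library. In camera on limma voom values and on the deposited log2 values, adjusted p was 0.0145 and 7.68e-03 for neuron markers, 0.0359 and 0.0197 for FMRFamide-like neuropeptides and 9.91e-03 and 0.0197 for heat shock proteins, and voom passed the endoplasmic reticulum list (0.0296). Without the low-count filter neuron markers (0.0264) and heat shock proteins (8.05e-03) passed. Heat shock proteins also passed camera with the replicate number as a block (adjusted p = 0.0493). Median and camera direction differed in sign for the iron, phase II, mitochondrial unfolded protein response and autophagy lists, whose medians were -0.11, -0.005, -0.06 and -0.03 with camera pointing up.

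Replicates were far closer to each other than to the other group. Across genes, Pearson's r of log2 CPM was 0.9958 between the mock RNAi libraries, 0.9913 between the ets-4 RNAi libraries and 0.968 to 0.974 between groups, where genes are not independent replicates. A first principal component with 81.0% of the variance separated the groups, and a second with 12.99% separated the ets-4 RNAi libraries from each other. On the first, ets-4 RNAi replicates 1 and 2 also differed (46.7 and 32.5). The ets-4 RNAi pair varied more than the mock RNAi pair, with an SD of log2 differences of 0.302 against 0.166 over 11730 genes with a mean of at least 50 counts. Chi-square per degree of freedom was 5.02 within the mock RNAi pair and 13.2 within the ets-4 RNAi pair, so in neither pair did the counts agree within sampling noise, against 114 to 133 across groups. The biological coefficient of variation was 8.24%.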

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

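The alternatives were planned before the data were examined, apart from the member counts of lists without each library. ets-4 and rege-1 kept their direction and their calls in every alternative run, with log2 changes between -2.49 and -2.04 for ets-4 and between -2.32 and -2.07 for rege-1 when single libraries were left out. Scaling mattered little: DESeq2-style factors, upper-quartile factors, totals only and library sizes without vitellogenin and major sperm protein genes gave 2918, 2837, 2717 and 2850 called genes, of which 2781, 2707, 2699 and 2792 were among the 2817 reported, and the share that fell stayed between 54.7% and 59.99%. DESeq2 called 2388 genes, limma voom 2854, limma on the deposited log2 values 2688 and edgeR without a low-count filter 3197. Requiring 5 CPM in 2 libraries left fewer genes to test and gave 555 genes changed at least 2-fold, 97 higher and 458 lower. An adjusted p under 0.01 left 1308 genes, 417 higher and 891 lower, and at least 2-fold left 918, 153 higher and 765 lower, both by construction. With the correlation estimated in camera, a version with little power at 2 libraries per group, 0 lists passed, at adjusted p-values of 0.311 and above. At the preset correlation 16 passed, and by fry 9 of these and 3 others. Leaving out single libraries gave 796 to 5352 called genes, 189 to 2493 higher and 607 to 2859 lower, and 534 to 1434 genes changed at least 2-fold, 93 to 208 higher and 439 to 1226 lower. The counts below 2817 came without a mock RNAi library, when the spread was estimated from the ets-4 RNAi pair, and those above came without an ets-4 RNAi library, when it was estimated from the closer mock RNAi pair. Of the genes called without mock RNAi replicate 1 or 2, 888 of 891 and 795 of 796 were among those reported. The cuticle collagen list turned from camera up to camera down without ets-4 RNAi replicate 2 (median -0.77, adjusted p = 1.11e-08), with medians from -0.77 to -0.25 over the libraries left out and adjusted p-values up to 0.974; the cause was not tested. With the replicate number as a replicate block, edgeR called 3933 genes, 1873 of them higher and 2060 lower, and 20 lists passed, with those of DAF-16 repressed genes (adjusted p = 0.0122), histones (0.0292), transporters (0.0435) and heat shock proteins (0.0493) newly past the threshold. The fit without the block stayed the main one because nothing in the labels says that a number marks a shared culture or day. Deviations of same-numbered libraries correlated at 0.193 over 11730 genes, with 2 pairs only. Counting every result under every alternative, tests of named genes came out the same in 2171 cases, past the threshold where they had not been in 9 and no longer past it in 128, of which 49 and 61 were without mock RNAi replicates 1 and 2. Tests of lists came out the same in 498 cases, newly past the threshold in 34, no longer past it in 35, of which 16 were with the estimated correlation, and turned in 1. Not run were DESeq2 for lists, pseudocounts of 1 and 8 on the deposited table, which is already on a log2 scale, and the removal of ribosomal RNA genes, none of which matched in the table. Depth limits the folds of genes near 0 counts. In the simulations with 2 libraries per group, changes of 1.5-fold were called in 28.4% or 50.1% of cases, depending on the dispersions. These shares may not carry over to the data. Only 200 of 14756 genes were changed in each simulated set, against 2817 called here, and both groups were given the same dispersions.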

Other observations

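The tests in this part were chosen after the data were seen. The prediction for neighbouring genes was written before its test was run; the others were written after, and members of families were named after their values were seen. A scan of 187 families of genes with the same symbol stem and at least 8 tested members (Fisher's exact test, one-sided, Benjamini-Hochberg adjusted) called 13 families as falling and 9 as rising, some of them genes of the fixed lists. The exact test treats genes as independent, a limit that applies to every p of this scan. The clec, cyp, msp and ribosomal genes it called were lost as lists with an estimated correlation (camera adjusted p = 0.403, 0.573, 0.573 and 0.311). That version of camera had little power with 2 libraries per group. The subunits of the vacuolar proton pump, which acidifies lysosomes, fell in 17 of 20 cases and rose in 0 (exact test adjusted p = 5.05e-12), by a median of -0.32, with the intestinal subunit vha-6 at -1.12 ± 0.06, vha-1 at -0.49 ± 0.07 and vha-10 at -0.42 ± 0.05. Aspartyl proteases fell in 8 of 11 cases (adjusted p = 1.40e-04; median -2.43): beside asp-12, asp-6 went from 3707 to 321 CPM (-3.53 ± 0.05) and asp-5 from 1347 to 296 CPM (-2.19 ± 0.06), while asp-4 and asp-13 (0.38 ± 0.09) rose. Acyl-CoA synthetases fell in 10 of 22 cases (adjusted p = 1.74e-03), among them acs-14 (-0.97 ± 0.07) and acs-22, and acs-3 rose (1.07 ± 0.09). Acyltransferases of the acl family fell in 7 of 13 (adjusted p = 5.49e-03), with acl-7 at -1.07 ± 0.08 and acl-4 at -0.96 ± 0.06, and the nspg genes fell in 8 of 12 (adjusted p = 3.02e-04; median -0.94). Members also fell among the cdh cadherins (5 of 9, adjusted p = 0.0283), oac acyltransferases (9 of 25, adjusted p = 0.0219), nas astacin proteases (10 of 32, adjusted p = 0.0331), ptr patched-related genes (8 of 23, adjusted p = 0.0370) and math genes (8 of 23, adjusted p = 0.0370; median -0.03). The other falling families were clec, spp and ech.

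In the other direction, 7 of 8 subunits of the cytosolic chaperonin rose by a median of 0.20 (exact test adjusted p = 6.40e-06), cct-8 by 0.30 ± 0.07 and cct-1 by 0.29 ± 0.05. Translation initiation factors rose in 8 of 25 cases and fell in 0 (exact test adjusted p = 0.0108, median 0.13), as in eif-3.J (0.40 ± 0.09). The puf genes, which encode RNA-binding proteins, rose in 5 of 8 (exact test adjusted p = 3.66e-03). The scan did not match families with other genes on abundance, and small changes are easier to call in well-counted genes. Random lists matched to ribosomal protein genes on mean expression had a median of 0.0884. Whether these small rises exceed those of equally abundant genes was not tested. The scan also called 2 families that camera had not called as lists: the 109 collagens, with 24 rising (exact test adjusted p = 9.66e-05) at a median of -0.47, and the 63 glucuronosyltransferases, with 23 rising (adjusted p = 8.94e-09). The other rising families were rpl, rps, cyp and msp. Under 5 scalings the medians of the vha, asp, acs, acl, nspg, cct, eif and puf families kept their signs. The chaperonin had 5 to 7 members rising and the puf family 4 to 5, and the members of the other 6 of these that fell or rose were as many under each scaling.

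By list medians molting genes fell while yolk and oocyte genes rose, and a difference in developmental stage at harvest is a candidate explanation. For molting, yolk and oocyte lists no call held in camera with an estimated correlation, which had little power here (adjusted p = 0.573, 0.573 and 0.604). By fry none held either (adjusted p = 0.0566, 0.0988 and 0.104). Between the 2 ets-4 RNAi libraries, molting genes differed by a median of -0.68 (95% bootstrap interval over genes -0.89 to -0.33), yolk genes by 0.41 and oocyte genes by 0.14, so the library further from the mock RNAi group in molting genes was also further in yolk and oocyte genes. Sperm genes went the other way, with that library nearer the mock RNAi group (-0.36 for major sperm proteins and -0.24 for other sperm genes, with group medians of 0.80 and 0.33). The mock RNAi libraries differed by 0.03 in molting genes and 0.02 in oocyte genes but by 0.29 in yolk genes, so yolk genes also moved between replicates without molting genes, which weakens the link. The test has 1 pair of libraries, and whether such a difference would come from the timing of harvest or from the knockdown itself was not tested.

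For the falls among intestinal, immune and peroxisomal genes, a graded stage difference as the whole cause predicted the ratio of molting genes. The ratio is the difference between the 2 ets-4 RNAi libraries over the group change. It was 0.584 (95% bootstrap interval 0.300 to 0.793) for molting genes and 0.105 (0.0346 to 0.201) for the 39 immune effectors. The prediction failed for the immune effectors, but the test cannot decide, because lists that follow stage need not share a ratio. Sperm genes, as given above, moved between these libraries against their group change, and only 1 pair of libraries was available. The explanation thus stays open for immune effectors. It stays open also for intestine markers (0.129, -0.528 to 0.391), beta-oxidation genes (0.254, -7.06 to 1.06) and C-type lectins (0.361, 0.162 to 0.614), whose intervals overlap that of molting genes. The immune, intestine and beta-oxidation lists pooled to 0.146 (0.0638 to 0.264, 101 genes) and with lectins and lipases to 0.217 (0.141 to 0.315, 240 genes), and the smaller pool was chosen after both had been seen, so neither decides. The first version, on 522 called genes outside the molting and collagen lists (0.140, 0.118 to 0.160), excludes nothing, because its selection favours small spread. A smaller share of intestinal RNA as the whole cause is argued against by the yolk genes, which are transcribed in the adult intestine. Their median lay 1.82 above that of the intestine markers (0.640 to 3.05). The argument is weak, because it rests on 6 yolk genes, of which vit-2 and vit-6 did not pass the test. The marker list also holds genes that are not specific to the intestine. Yolk genes also differed by 0.29 between the mock RNAi libraries, and a stage difference, not excluded above, could have moved them separately.

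Ribosomal protein genes rose as a group, and 2 explanations were tested. Library scaling would move genes of the same abundance alike. Random lists matched on mean expression had a median of 0.0884, so part of the rise was shared with other genes of that abundance. The ribosomal median lay 0.212 above that value, and 0 of 10000 random lists reached the ribosomal median. Random lists hold unrelated genes, so they may vary less than a list whose genes move together. A graded stage difference as the whole cause was predicted to give ribosomal protein genes the ratio seen for molting genes. Their ratio was -0.0615 (95% bootstrap interval -0.127 to 0.0219) against 0.584, so the prediction failed. That does not decide the question, because lists that follow stage need not share a ratio and only 1 pair of libraries was available. With an estimated correlation the list itself gave a camera adjusted p of 0.311, in a test with little power at 2 libraries per group. The rise may still be one shared shift of few libraries.

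Genes that fell at least 2-fold tended to lie next to each other on the chromosomes. Among 14389 tested genes in annotation order, 103 adjacent pairs had both members lower, against a median of 43 (95% range 31 to 55) in 10000 random placements within chromosomes (permutation p = 0.0001, the smallest they can give). Runs of 5 genes were clec-62 to clec-66 on chromosome II (12893062 to 12906644), clec-67, F56D6.15, clec-70, clec-71 and clec-72 on chromosome IV (3922165 to 3947362) and spp-3, spp-2, spp-6, spp-4 and spp-5 on chromosome X (7314969 to 7320354). Tandem families may account for part of this: 33 of the pairs belonged to 1 family by symbol, against a random median of 2, while pairs of different named families numbered 14, within the random range of 6 to 20. The other 56 pairs held a gene without a family name, against a random median of 28 (18 to 38), so whether tandem families account for the whole excess stays open. These 56 pairs were counted after the other values were seen.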
